A study of Mus musculus with 8 samples.

How the data were processed

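The study measured RNA of mouse cells by bulk RNA sequencing. Group 2 innate lymphoid cells (ILC2s, tissue-resident lymphocytes without antigen receptors that make type 2 cytokines) came from lung and CD8 T cells from spleen of wild-type mice, per the labels. The cell types were cultured together for 3 days at a ratio of 5:1, or separately, and were then isolated by flow cytometry, per the labels. RNA was extracted with Trizol and libraries were made with a SMART-Seq v4 low-input kit, per the labels' protocols. There were 4 groups of 2 libraries each. Nothing in the labels says that the replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

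The authors deposited 2 tables of whole-number read counts per gene symbol, a table of 17642 genes for the CD8 T cells and a table of 18389 genes for the ILC2s, each with 4 libraries. The submitters' processing notes name Trimmomatic 0.38, HISAT2 2.1.0, SAMtools 1.9, StringTie 2.1.3b and the build mm10. The role of each tool, the gene annotation, the strand setting and any filter on low counts are not given in the sources used here. No value in either deposited count table is 0, and the lowest count is 1. A gene with 0 reads in at least 1 library of a table is therefore not in that table, which leaves out transcripts that appear in only 1 of the groups. Of the symbols, 95.7% in each table matched the RefSeq annotation of GRCm38.p6, the assembly of mm10, from which gene positions were taken. Counting was not described for reads shared between similar genes, so values of granzyme family members, Bcl2a1b, Serpina3g, Serpinb9b, Psme2, the class I genes H2-K1 and H2-D1 and the antigen receptor constant regions are uncertain. Reads of overlapping antisense genes cannot be separated, because the strand setting is not given.

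The total count per library ran from 48072595 to 67076905 reads, and the ILC2 libraries labelled co-cultured had the lowest totals. The 10 most abundant genes held 6.12% to 9.13% of the counts. Replicates were compared before use: their counts differed by more than sampling noise (chi-square per gene from 13.9 to 28.75), and Pearson's r of log2 CPM (read counts scaled by the library total) across genes was 0.9945 to 0.9977, so each library was used as 1 replicate. CPM values in the text are counts divided by the library total, given as mean ± SD over n = 2 libraries. Log2 changes come from the fitted models and include the scaling factors, so they can differ from the ratio of CPM means.

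Each cell type was tested separately on the deposited counts with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05). SE of a log2 change is its size divided by the square root of the F statistic. The comparison is always libraries labelled co-cultured against libraries labelled alone. The filter left 15948 genes for CD8 T cells and 16739 for ILC2s. The difference between the responses of both cell types was tested as an interaction over all 8 libraries and 15532 genes found in both tables. The design left 2 residual degrees of freedom per cell type and 4 in the interaction model. The quasi-likelihood test adds variance information from other genes, with prior degrees of freedom of 10.4 (CD8 T cells), 9.2 (ILC2s) and 11.5 (interaction). The p-value of a gene therefore rests in large part on the spread of other genes. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were used as alternatives, with other scalings, filters and left-out libraries. Ranges of a list's or gene's adjusted p over the alternatives leave out camera with an estimated correlation and fry, which are given apart. Summaries and plots were made in Python 3.11.15 with pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

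There were 32 gene lists, 19 of biological processes, 10 of cell type markers and 3 of RNA quality or handling. They covered cytotoxic effectors, T cell activation, naive and memory genes, inhibitory receptors, type 1 and type 2 cytokine genes, MHC class I and class II presentation, costimulatory ligands, endocytosis, interferon response, cell cycle, glycolysis, oxidative phosphorylation, cholesterol synthesis, unfolded protein response, interleukin-2 and STAT5 targets, chemokines and migration, and apoptosis. The marker lists were for ILC2s, CD8 T cells, CD4 and regulatory T cells, B cells, NK cells, monocytes and macrophages, dendritic cells, granulocytes and mast cells, stroma and epithelium, and red cells and platelets. The last 3 lists were handling stress, ribosomal protein and mitochondrially encoded genes. Lists with at least 5 tested members were tested with camera (preset correlation 0.01), which compares a list with the other genes, and with camera using an estimated correlation. The latter takes its degrees of freedom from the residual ones, 2 per cell type and 4 in the interaction. Few lists can pass it after adjustment, so a lost call is weak evidence against a list. Lists were also tested with fry, whose directional p asks whether the members move, on balance, one way. The share of partner-cell RNA was estimated as the median, over identity markers at least 20 times higher in the partner cultured alone, of a library's CPM as a percent of the partner's CPM. It is descriptive.

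Genes were named by a rule. It took the 5 largest rises and 5 largest falls among called genes with a mean log2 CPM of at least 4 whose groups did not overlap, leaving out predicted and clone-named genes. It also took members of each biology list with the smallest adjusted p (at most 3 per list), the 3 most abundant members of each marker list, and genes fixed in advance. The fixed genes were Cd8a, Gzmb, Prf1, Ifng, Tnf, Il2ra, Cd69 and Mki67 in CD8 T cells, and Gata3, Il1rl1, Il5, Il13, Areg, Cd74, H2-K1, H2-Ab1, Cd80, Cd86, Icosl, Cd274 and Mki67 in ILC2s. Not every gene the rule took is named. Groups, tests, lists, the naming rule and the alternatives were fixed before the data were examined, except those said to be chosen later.

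The tests were run on simulated counts with 200 changed genes per comparison, as many rising as falling, and 50 at each size within a cell type. Nearly all simulated genes were left unchanged, whereas 60.9% and 66.3% of genes were called in CD8 T cells and ILC2s. The rates below therefore do not show how the tests do where most genes change or the scaling fails. At log2 sizes of 0.5, 1, 2 and 4, the test recovered 62%, 66%, 90% and 98% of changed genes over the 15948 genes of the CD8 comparison, with 9 false calls among 167. Over the 16739 genes of the ILC2 comparison it recovered 26%, 72%, 88% and 98%, with 4 false calls among 146. The interaction test recovered 80% at a log2 size of 2 over 15532 genes, with 8 false calls among 168.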

Results

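The transcriptomes of lung ILC2s and splenic CD8 T cells were measured after 3 days of co-culture at 5:1 and after culture of each cell type on its own, with 2 libraries in each of 4 groups. The series addresses whether ILC2s take up antigen, present it to CD8 T cells and activate them. The comparisons here asked which genes differed between co-cultured and separately cultured cells within each cell type, and whether the difference was alike in both. Library totals were 52664716 and 57077134 counts for CD8 T cells alone and 66170866 and 67076905 for those co-cultured, and 60738117 and 55417551 for ILC2s alone and 48471801 and 48072595 for those co-cultured. Marker genes of T cells, macrophages and stroma were higher in the ILC2 libraries labelled alone than in those labelled co-cultured, so groups are called labelled alone and labelled co-cultured throughout. Every direction given is that of the labels.

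In CD8 T cells labelled co-cultured, Ifng, Csf2 and Il3 were lower and Ccr9, Gzma and Prf1 higher than in those labelled alone. Ifng, which encodes interferon gamma, stood at 1552 ± 54.7 CPM labelled alone and 105.9 ± 0.18 CPM labelled co-cultured (SD, n = 2), a log2 change of -3.95 (SE 0.075, edgeR adjusted p = 4.6e-12). Csf2, the gene of the growth factor GM-CSF, fell from 70.9 ± 30.7 to 0.55 ± 0.027 CPM (log2 change -7.09, SE 0.307). In the other direction, Ccr9, a chemokine receptor of gut- and thymus-homing lymphocytes, rose from 1.54 ± 0.46 to 300.6 ± 3.01 CPM, a log2 change of 7.54 (SE 0.133, edgeR adjusted p = 3.5e-12). Ccr9 lies on chromosome 9 at 123767211 to 123783457 and Ifng on chromosome 10 at 118441046 to 118445894, both protein-coding genes of GRCm38.

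Among genes with a mean log2 CPM of at least 4, the largest rises beside Ccr9 were those of Filip1 (log2 change 4.54, SE 0.20), Osgin1 (4.52, SE 0.133), the ATP-gated channel gene P2rx7 (4.50, SE 0.159) and Cd7, a lymphocyte surface glycoprotein (3.82, SE 0.084). Filip1 rose from 6.99 ± 3.03 to 172.6 ± 16.9 CPM and Cd7 from 16.5 ± 0.62 to 245.2 ± 13.2 CPM. Within the same limit, the largest falls after Csf2 were those of Serpina3g, a serine protease inhibitor (-5.79, SE 0.149), Cd74, the invariant chain of MHC class II (-5.08, SE 0.12), Lad1 (-4.89, SE 0.164) and Il3, the interleukin-3 gene (-4.87, SE 0.111). Il3 stood at 55.6 ± 0.51 CPM labelled alone and 2.01 ± 0.11 CPM labelled co-cultured. It neighbours Csf2 on chromosome 11, at 54265085 to 54267279 against 54247270 to 54249899.

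**Figure D1:**
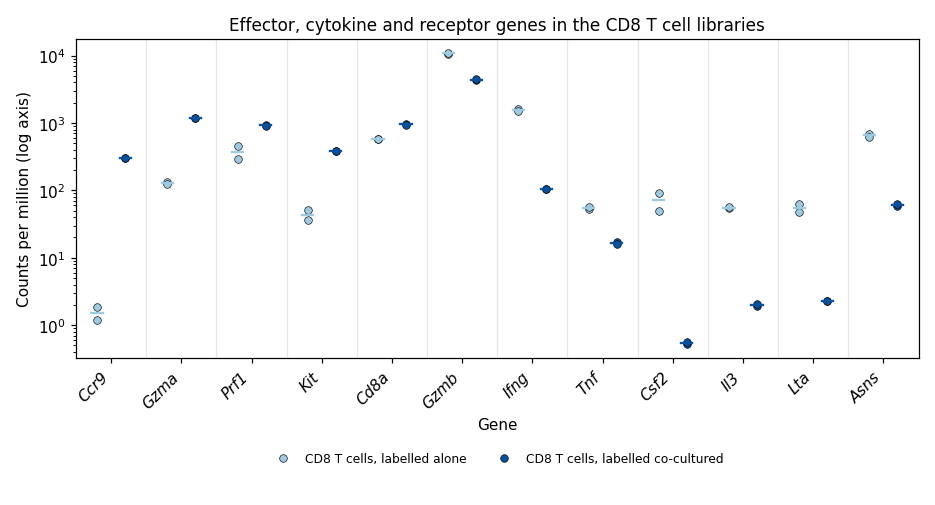
CPM on a log axis for 12 genes in the 4 CD8 T cell libraries. Points are single libraries and short lines are means of 2 libraries. Ifng, Tnf, Csf2, Il3, Lta, Gzmb and Asns lie lower in the libraries labelled co-cultured, and Ccr9, Gzma, Prf1, Kit and Cd8a lie higher, with Ccr9 at 300.6 against 1.54.

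Of 23 cytotoxic effector genes tested in CD8 T cells, 17 rose, 4 fell and 2 did not pass. Gzma, encoding granzyme A, rose from 129.3 ± 6.04 to 1185 ± 5.13 CPM (log2 change 3.12, SE 0.073). Prf1, the perforin gene, rose from 369.2 ± 111.6 to 918.8 ± 14.8 CPM (log2 change 1.23, SE 0.147), and Serpinb9b, a granzyme inhibitor of the serpin family, rose by a log2 change of 2.71 (SE 0.09). Gzmb, encoding granzyme B and the most abundant of these genes, fell from 10760 ± 130.1 to 4409 ± 125.0 CPM (log2 change -1.37, SE 0.069, edgeR adjusted p = 8.3e-09). Summed over the list, CPM were therefore lower labelled co-cultured (12870 ± 45.3) than labelled alone (15910 ± 526.9). Camera placed the list above other genes (adjusted p = 2.8e-04 with the preset correlation, adjusted p = 0.46 with an estimated correlation).

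The type 1 cytokine genes split in CD8 T cells, with 10 of 21 up and 11 down, and the falls were the larger. Besides Ifng and Csf2, Lta, encoding lymphotoxin alpha, fell from 55.1 ± 11.4 to 2.30 ± 0.0009 CPM (log2 change -4.66, SE 0.149), and Tnf fell from 55.3 ± 2.63 to 16.6 ± 0.56 CPM (log2 change -1.81, SE 0.088). Of 18 type 2 cytokine genes tested, from 26 listed, 14 fell, 1 rose and 3 did not pass. Penk, which encodes proenkephalin, fell by 2.97 on the log2 scale (SE 0.094) and the chemokine receptor gene Ccr8 by 2.62 (SE 0.092). Markers of other cells moved both ways. They fell in 13 of 21 cases for ILC2 identity and 5 of 9 for dendritic cells, though neither list was called in the main test. Both these lists share members with the type 2 list, such as Ccr8 with ILC2 identity. NK cell genes (4 up and 1 down of 9), CD4 and regulatory T cell genes (4 and 1 of 7) and stroma genes (3 and 1 of 4) went the other way. The type 1 and type 2 lists lay below other genes by camera (adjusted p = 0.0052 and 4.0e-08, adjusted p = 0.46 for both with an estimated correlation). The type 1 call ended without the low-count filter (adjusted p = 0.457), with limma-voom (0.602) and in a fit of all 8 libraries (0.154, with a median log2 change of 0.047 there), in a range of 3.3e-05 to 0.602 over 13 alternatives.

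Activation markers moved both ways. Among 25 T cell activation genes in CD8 T cells, 9 rose, 12 fell and 4 did not pass, and camera found no shift of the list (adjusted p = 0.52). Cd38, an ectoenzyme gene, rose from 28.2 ± 3.95 to 207.8 ± 10.9 CPM, while the transcription factor gene Batf3 (log2 change -3.55, SE 0.161) and the transferrin receptor gene Tfrc (-1.34, SE 0.072) fell. Il2ra, encoding the high-affinity interleukin-2 receptor chain, fell from 755.0 ± 20.4 to 642.9 ± 11.4 CPM. Cd69, an early activation marker, stood at 157.8 ± 0.19 CPM labelled alone and 163.4 ± 8.70 CPM labelled co-cultured (log2 change -0.03, SE 0.071, edgeR adjusted p = 0.73). Cd8a itself rose from 575.0 ± 6.98 to 951.5 ± 20.9 CPM (log2 change 0.65, SE 0.066).

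Genes of quiescent T cells rose more often than they fell, with 11 of 22 up, 5 down and 6 not passing. Examples were the insulin-like growth factor binding protein gene Igfbp4 (log2 change 2.20, SE 0.077), the kinase gene Txk (2.59, SE 0.105) and Il6st, encoding the interleukin-6 receptor subunit gp130 (2.11, SE 0.089). Of 17 genes listed for inhibitory receptors and exhaustion, 9 rose, 3 fell and 5 did not pass, led by the ectonucleotidase genes Nt5e (32.4 ± 6.91 to 335.1 ± 29.2 CPM) and Entpd1 (8.53 ± 1.85 to 66.2 ± 6.23 CPM), which encode the CD73 and CD39 enzymes that make extracellular adenosine. Of 28 chemokine and migration genes, 16 rose, 9 fell and 3 did not pass. The camera adjusted p were 0.0028, 0.017 and 0.0015 for these 3 lists, and adjusted p = 0.46 for each with an estimated correlation. The inhibitory and migration calls ended without genes at least 4 times higher in ILC2s labelled alone (adjusted p = 0.564 and 0.19), without the low-count filter (0.074 for both) and with limma-voom (0.0951 for both). Over 13 alternatives these adjusted p ranged from 0.00246 to 0.564 and from 0.00129 to 0.19.

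Of 23 unfolded protein and amino acid response genes in CD8 T cells, 21 fell and 1 rose. Asns, the asparagine synthetase gene, fell from 660.5 ± 45.2 to 60.8 ± 2.91 CPM (log2 change -3.52, SE 0.081, edgeR adjusted p = 1.4e-11), Phgdh, of serine synthesis, from 885.2 ± 62.4 to 215.8 ± 11.1 CPM, and the stress transcription factor gene Atf3 by 2.66 on the log2 scale (SE 0.10). Of 26 oxidative phosphorylation genes 23 fell, among them Ndufa4 (-2.40, SE 0.085) and the cytochrome c gene Cycs (-1.56, SE 0.078). Of 22 cholesterol synthesis genes 16 fell and 3 rose, with Idi1 at -1.05 (SE 0.068) and Fdps at -0.96 (SE 0.068). Ribosomal protein genes fell in 78 of 83 cases with none rising. Camera adjusted p were 6.6e-20, 2.4e-09, 2.8e-04 and 1.9e-19 in this order, and with an estimated correlation the first had an adjusted p = 0.25 and the other three an adjusted p = 0.46.

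Of 40 cell cycle genes in CD8 T cells, 24 fell, 8 rose and 8 did not pass (camera adjusted p = 0.0039, adjusted p = 0.58 with an estimated correlation). Tyms and Ccne2, of DNA synthesis and entry into S phase, fell by 1.92 (SE 0.124) and 2.03 (SE 0.14) on the log2 scale. Mki67, the proliferation marker, stood at 81.8 ± 7.71 and 80.3 ± 5.24 CPM (log2 change -0.11, SE 0.084, edgeR adjusted p = 0.29). Among 25 MHC class I presentation genes, 14 fell, 6 rose and 5 did not pass. The proteasome activator gene Psme2 fell (-1.18, SE 0.069) and the peptide-loading gene Tapbp rose (0.84, SE 0.072). The class I list lay near the threshold (camera adjusted p = 0.0496, adjusted p = 0.46 with an estimated correlation) and its call ended without CD8 co-cultured replicate 2 (adjusted p = 0.112) and in 8 of the other alternatives, with a range of 0.0358 to 0.112 over 13.

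The other biology lists were not called by camera in CD8 T cells. Fry called 4 of them, all downward: MHC class II (fry adjusted p = 0.012), costimulatory ligands (0.016), apoptosis (0.012) and interleukin-2 and STAT5 targets (0.043). It did not call interferon response (0.76), glycolysis (0.59) or endocytosis (0.68). The adjusted p given below are those of camera. For MHC class II presentation 7 of 20 genes rose and 9 fell (camera adjusted p = 0.22), with H2-Aa at 9.56 ± 1.52 CPM labelled alone and 11 and 10 reads in the libraries labelled co-cultured, and the cathepsin B gene Ctsb at 1.18 (SE 0.07). Of 19 costimulatory ligand genes 5 rose and 11 fell (adjusted p = 0.066), among them Tnfsf8 (-1.90, SE 0.094) and Cd80 (-1.85, SE 0.191), and the list was called without CD8 co-cultured replicate 1 (adjusted p = 0.0462, range 0.00554 to 0.221 over the alternatives). The interferon response counted 13 up and 16 down of 37 (adjusted p = 0.97), with Usp18 up (1.55, SE 0.079) and Isg20 down (-2.45, SE 0.177). Glycolysis counted 8 up and 9 down of 23 (adjusted p = 0.70), with Hif1a up from 353.9 ± 39.1 to 1061 ± 27.7 CPM. Endocytosis counted 10 up and 12 down of 29 (adjusted p = 0.93), interleukin-2 and STAT5 targets 7 up and 13 down of 23 (adjusted p = 0.32), with Socs3 up (2.00, SE 0.101), and apoptosis genes 6 up and 12 down of 23 (adjusted p = 0.24), with Bcl2l11 up (1.56, SE 0.084).

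ILC2 identity genes summed to 850.6 ± 17.7 and 1204 ± 48.7 CPM in CD8 T cells labelled alone and co-cultured, against 5157 ± 7.99 and 12980 ± 111.5 CPM in ILC2s. Over the 8 identity markers that were at least 20 times lower in CD8 T cells labelled alone, the median level was 0.489% and 0.461% of that in ILC2s labelled alone for the libraries labelled alone, and 0.207% and 0.204% for those labelled co-cultured. Of 21 ILC2 identity genes 5 rose and 13 fell (camera adjusted p = 0.18, and 0.0127 in the fit of all 8 libraries, range 0.0127 to 0.608), but Kit, a stem cell factor receptor gene, rose from 43.4 ± 9.95 to 381.3 ± 4.41 CPM. Cd4 stood at 1.11 ± 0.14 and 9.56 ± 0.29 CPM, and the CD4 and regulatory T cell list counted 4 up and 1 down of 7 (adjusted p = 0.066, and 0.0299 without CD8 alone replicate 2, range 0.0299 to 0.19). Of 18 CD8 T cell identity genes 8 rose and 5 fell (adjusted p = 0.26). NK cell genes counted 4 up and 1 down of 9 (adjusted p = 0.066, range 4.3e-04 to 0.492), B cell genes 1 and 1 of 8 (0.82), monocyte and macrophage genes 2 and 3 of 7 (0.88) and dendritic cell genes 1 and 5 of 9 (0.094, and 0.0488 without CD8 co-cultured replicate 1, range 0.0176 to 0.178). Too few genes for a list test were measured for stroma (3 up and 1 down of 4), granulocytes and mast cells (1 up and 2 down of 3), platelets (2 of 2 down, with Itga2b at 17.0 ± 0.025 and 0.63 ± 0.058 CPM) and mitochondrially encoded genes (1 of 2 down). Of 16 handling stress genes 3 rose and 9 fell (adjusted p = 0.12).

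In total 4810 genes were higher and 4901 lower in CD8 T cells labelled co-cultured, 60.9% of the 15948 tested. Of these, 1532 and 1711 changed at least 2-fold. Camera called 12 of 28 lists, 4 above and 8 below other genes. With an estimated correlation it called 0, with 1 list at an unadjusted p under 0.05, while fry called 21.

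The ILC2 libraries differed by whole sets of genes of other lineages. Among genes with a mean log2 CPM of at least 4, the largest falls in ILC2s labelled co-cultured were those of Lox, encoding the collagen cross-linking enzyme lysyl oxidase (1027 ± 22.9 CPM labelled alone and 0.093 ± 0.043 labelled co-cultured), the collagen chaperone gene Serpinh1 (754.0 ± 73.7 and 0.10 ± 0.087), the neutrophil-attracting chemokine gene Cxcl5 (901.4 ± 260.2 and 0.16 ± 0.13), the matrix protease gene Mmp3 (722.5 ± 35.7 and 0.13 ± 0.014) and the collagen gene Col1a2 (1400 ± 113.3 and 0.43 ± 0.11). ILC2 genes went the other way. Gata3, the transcription factor of type 2 lymphocytes, rose from 414.3 ± 20.9 to 1277 ± 56.3 CPM (log2 change 1.84, SE 0.118, edgeR adjusted p = 1.0e-07), and Il5, encoding interleukin-5, from 327.7 ± 21.9 to 1493 ± 1.99 CPM (log2 change 2.40, SE 0.118). Cd8a stood at 253.8 ± 6.19 CPM in ILC2s labelled alone and at 6.42 ± 0.48 CPM in those labelled co-cultured with CD8 T cells (log2 change -5.09, SE 0.141, edgeR adjusted p = 1.5e-10). Gata3 lies on chromosome 2 at 9857078 to 9887953 and Il5 on chromosome 11 at 53720794 to 53725103 of GRCm38.

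Of the falls just named, those of Lox, Serpinh1, Cxcl5 and Mmp3 rest on 2 to 12 reads per library labelled co-cultured, so no fold is given for them. Within the same limit and without predicted genes, the largest rises were those of Gipr, a receptor gene for an incretin hormone (log2 change 6.30, SE 0.221), Igsf9 (4.70, SE 0.144), Smtnl2 (4.28, SE 0.218), Dysf, the gene of the membrane repair protein dysferlin (3.94, SE 0.166), and Itga7, an integrin chain gene (3.81, SE 0.133). Gipr went from 0.49 ± 0.18 to 33.4 ± 1.07 CPM and Itga7 from 15.7 ± 0.42 to 190.2 ± 2.37 CPM.

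**Figure D2:**
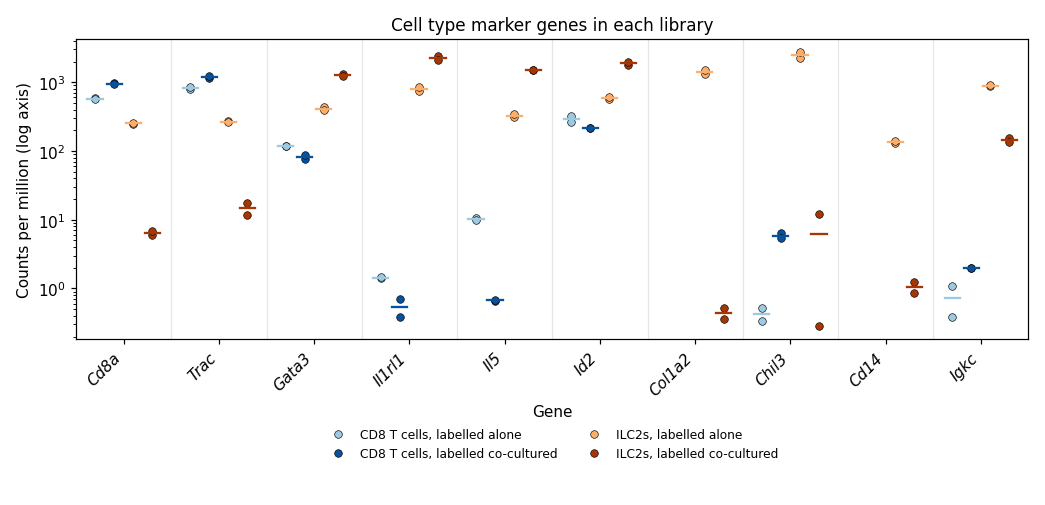
CPM on a log axis for 10 marker genes in the 8 libraries. Points are single libraries and short lines are means of 2 libraries, and no points are drawn for Col1a2 and Cd14 in CD8 T cells, whose table lacks them. The ILC2 libraries labelled alone hold Cd8a at 253.8, Col1a2 at 1400 and Chil3 at 2469, against 6.42, 0.43 and 6.23 in the ILC2 libraries labelled co-cultured.

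Of 25 ILC2 identity genes 22 rose, 1 fell and 2 did not pass, with a median log2 change of 1.55 (camera adjusted p = 1.8e-09, adjusted p = 0.24 with an estimated correlation). Il1rl1, encoding the interleukin-33 receptor, rose from 796.8 ± 83.7 to 2242 ± 222.7 CPM and the transcription factor gene Id2 from 592.7 ± 24.9 to 1879 ± 134.1 CPM. Il13 rose from 1.95 ± 0.28 to 10.4 ± 2.51 CPM, and Areg, encoding amphiregulin, from 95.5 ± 2.095 to 226.3 ± 19.2 CPM. Scaling the libraries to the ILC2 identity genes, a choice made after these values were seen, lowers all changes by a similar amount (median over all genes -1.503, against -0.01 under TMM), so rises given for ILC2s are relative to the TMM scaling. Under the scaling to identity genes the change of Il1rl1, a member of that list, was 0.20 (SE 0.125) and no longer passed. The type 2 cytokine list shares members with the ILC2 identity list, such as Gata3 and Il5. Of 23 type 2 cytokine genes 16 rose, 6 fell and 1 did not pass (camera adjusted p = 0.033, adjusted p = 0.31 with an estimated correlation). That call ended without ILC2 alone replicate 1 (adjusted p = 0.13), without ILC2 alone replicate 2 (0.149) under a stricter low-count filter (0.0742) and under the scaling to identity genes (0.29), in a range of 0.00133 to 0.29 over 14 alternatives. Il6 (428.7 ± 39.6 to 3.13 ± 0.070 CPM) and Csf2 (41.1 ± 7.57 to 1.72 ± 0.16 CPM) were among those that fell.

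Marker lists of other cells were higher in the libraries labelled ILC2 alone. Of 18 CD8 T cell identity genes 17 fell labelled co-cultured, among them the T cell receptor gene Trac (265.9 ± 6.15 to 14.6 ± 4.26 CPM). All 8 NK cell genes tested, of 11 listed, fell, as did all 7 monocyte and macrophage genes tested, of 16 listed. Chil3, a product of alveolar macrophages, stood at 2469 ± 354.9 and 6.23 ± 8.40 CPM, and Cd14 at 135.8 ± 5.52 and 1.04 ± 0.27 CPM. Of 11 stroma and epithelium genes 10 fell and 1 rose, of 9 dendritic cell genes 6 fell and 1 rose, and of 7 granulocyte and mast cell genes 6 fell, with the mast cell protease gene Cpa3 at 127.3 ± 18.9 and 19.1 ± 0.72 CPM. Camera adjusted p for these lists were 2.4e-14 for CD8 T cells and for stroma, 2.3e-04 for NK cells, 2.6e-07 for monocytes and macrophages, 7.3e-04 for dendritic cells and 0.025 for granulocytes and mast cells. With an estimated correlation each had an adjusted p = 0.24, except the last with an adjusted p = 0.32. B cell genes counted 2 up and 5 down of 14 (adjusted p = 0.19), with the antibody light chain gene Igkc at 894.3 ± 21.3 and 144.6 ± 12.7 CPM. CD4 and regulatory T cell genes counted 3 up and 4 down of 7 (adjusted p = 0.98), with Ctla4 up from 381.8 ± 9.93 to 1707 ± 32.0 CPM, and red cell and platelet genes 5 up and 2 down of 9 (adjusted p = 0.81).

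The planned estimate of T cell RNA found no marker 20 times higher in CD8 T cells than in ILC2s labelled alone. At the planned lower ratio of 5 there were 5 markers, with medians of 19.5% and 18.5% of the CD8 level in the libraries labelled ILC2 alone and 2.06% and 2.73% in those labelled co-cultured. Markers were kept only if low in the libraries labelled ILC2 alone. This choice caps the share there, so a larger share could not have appeared. With ILC2s labelled co-cultured as the reference, a choice made after the values were seen, 9 markers gave 21.9% and 23.7% labelled alone against 1.42% and 1.83% labelled co-cultured. That reference caps the share labelled co-cultured instead.

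Antigen presentation genes moved in both directions in ILC2s. Of 25 MHC class I genes 11 rose, 6 fell and 8 did not pass (camera adjusted p = 0.35). H2-K1, a classical class I heavy chain gene, rose from 5499 ± 448.3 to 11010 ± 300.6 CPM (log2 change 1.22, SE 0.103) and H2-D1 from 7173 ± 599.0 to 18710 ± 882.5 CPM, while the immunoproteasome gene Psmb10 (-1.82, SE 0.14) and Psme2 (-1.48, SE 0.124) fell. Of 20 MHC class II genes 6 rose and 12 fell (camera adjusted p = 0.35, fry adjusted p = 0.035, downward). Cd74 fell from 535.3 ± 8.02 to 150.0 ± 18.3 CPM and the cathepsin gene Ctsl from 422.0 ± 62.9 to 63.3 ± 4.16 CPM, whereas H2-Ab1, a class II beta chain gene, rose from 140.5 ± 12.2 to 271.0 ± 24.0 CPM and H2-Oa from 14.8 ± 1.88 to 46.7 ± 5.96 CPM. Scaled to the ILC2 identity genes, the changes of H2-K1, H2-D1 and H2-Ab1 became -0.28 (SE 0.125), 0.10 (SE 0.128) and -0.33 (SE 0.134). Macrophage and dendritic cell markers, whose cells express class II genes, moved with Cd74 and Ctsl.

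Of 22 costimulatory ligand genes in ILC2s 11 fell, 2 rose and 9 did not pass (camera adjusted p = 7.3e-04, adjusted p = 0.32 with an estimated correlation). The CD28 ligand genes Cd80 (9.60 ± 1.77 to 0.60 ± 0.17 CPM) and Cd86 (19.5 ± 0.43 to 1.92 ± 0.17 CPM) fell, as did Cd40 (-3.53, SE 0.171) and the adhesion gene Vcam1 (212.3 to 0.40 CPM). Markers of other lineages fell with them, in 7 of 7 cases for monocytes and macrophages (median log2 change -6.54), 6 of 9 for dendritic cells and 10 of 11 for stroma and epithelium. Icosl, encoding the ICOS ligand, rose from 8.54 ± 0.056 to 10.4 ± 0.58 CPM (log2 change 0.50, SE 0.161, edgeR adjusted p = 0.017). The call of Icosl ended without ILC2 alone replicate 1 (adjusted p = 0.0659), ILC2 alone replicate 2 (0.0733) or ILC2 co-cultured replicate 1 (0.0951) and in the fit of all 8 libraries (0.213). It turned negative under the scaling to identity genes, in a range of adjusted p of 2.7e-04 to 0.213 over 15 alternatives. Cd274, which encodes PD-L1, stood at 224.6 ± 23.4 and 188.7 ± 32.0 CPM (log2 change -0.03, SE 0.152, edgeR adjusted p = 0.86), and under the scaling to identity genes its change was -1.54 (SE 0.135) and passed. Of 30 endocytosis genes 15 fell and 4 rose (adjusted p = 0.025, adjusted p = 0.63 with an estimated correlation), among them the Fc receptor gene Fcgr3 (88.1 ± 8.27 to 4.22 ± 0.22 CPM), which fell with the macrophage markers.

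Of 38 interferon response genes in ILC2s 32 fell and 2 rose. T cell, macrophage and stroma markers fell with these and the lists that follow. Cxcl9 and Cxcl10, interferon-induced chemokine genes, fell from 509.6 ± 26.1 and 540.5 ± 7.001 CPM to 0.37 ± 0.031 and 0.32 ± 0.017 CPM, and Oasl2 fell from 114.1 ± 0.73 to 3.35 ± 0.29 CPM. Of 31 chemokine and migration genes 17 fell and 13 rose, with Ccl3 down by 7.33 on the log2 scale (SE 0.19). Of 21 cytotoxic effector genes 16 fell and 2 rose, with Gzmc at -6.72 (SE 0.163) and Serpinb9 at -4.94 (SE 0.144). T cell activation genes counted 14 down and 7 up of 25, with Egr2 (-4.95, SE 0.166) and Nr4a2 (-4.51, SE 0.163) down, naive and memory genes 15 down and 3 up of 22, and type 1 cytokine genes 11 down and 7 up of 20. Camera adjusted p for these 6 lists were 7.6e-14, 1.9e-05, 4.2e-18, 0.018, 2.2e-05 and 0.0047. With an estimated correlation the interferon, cytotoxic, naive and type 1 lists had an adjusted p = 0.24, the migration list an adjusted p = 0.32 and the activation list an adjusted p = 0.28. With limma-voom the activation, type 1 and migration calls ended (adjusted p = 0.1, 0.225 and 0.235).

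Of 23 glycolysis genes in ILC2s 19 rose and 2 fell, with a median above 0 under TMM and below 0 under the scaling to identity genes (camera adjusted p = 1.5e-05, adjusted p = 0.32 with an estimated correlation). The glycolytic enzyme genes Aldoa and Gpi1 rose from 3135 ± 11.8 to 10420 ± 491.4 CPM and from 866.7 ± 16.6 to 3020 ± 25.2 CPM, and the glucose transporter gene Slc2a3 from 216.7 ± 24.9 to 923.2 ± 31.8 CPM. Of 40 cell cycle genes 35 fell and none rose (adjusted p = 2.1e-08, adjusted p = 0.31 with an estimated correlation). T cell, macrophage and stroma markers fell with them, and the list summed to 9460 ± 527.1 CPM in CD8 T cells labelled alone, against 5311 ± 318.2 and 2081 ± 62.0 CPM in ILC2s labelled alone and co-cultured. Tyms stood at 87.5 ± 2.55 and 8.27 ± 0.66 CPM and Rrm2, of nucleotide synthesis, at 395.2 ± 7.76 and 48.2 ± 0.033 CPM. Mki67 did not pass, at 44.6 ± 6.80 and 40.3 ± 1.71 CPM (log2 change 0.07, SE 0.141, edgeR adjusted p = 0.69), and its change was -1.43 (SE 0.135) under the scaling to identity genes. Of 26 oxidative phosphorylation genes 19 fell and 1 rose, with Cycs down from 166.9 ± 2.35 to 31.2 ± 4.52 CPM (adjusted p = 0.033, adjusted p = 0.65 with an estimated correlation, 0.0714 without ILC2 co-cultured replicate 1, range 0.00247 to 0.104).

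Ribosomal protein genes in ILC2s counted 37 up and 9 down of 81 (camera adjusted p = 0.043, adjusted p = 0.75 with an estimated correlation), a call that ended without ILC2 alone replicate 2 (adjusted p = 0.0613) or ILC2 co-cultured replicate 2 (0.236) and whose median turned to -1.18 under the scaling to identity genes, with a range of 0.00526 to 0.833. Lists not called by camera were cholesterol synthesis (4 up and 12 down of 22, adjusted p = 0.15, with Cyp51 at -1.88), unfolded protein response (6 and 10 of 23, adjusted p = 0.35, with Slc7a11 at -5.28), apoptosis (7 and 10 of 24, adjusted p = 0.31, with Bcl2a1b at -3.87), inhibitory receptors (10 and 6 of 18, adjusted p = 0.34, with Prdm1 at 3.08) and handling stress (5 and 10 of 16, adjusted p = 0.35). Fry called the cholesterol (fry adjusted p = 0.0043), unfolded protein (0.027), apoptosis (0.032) and stress (0.013) lists, all downward. It called interleukin-2 and STAT5 targets upward (0.028) and did not call inhibitory receptors (0.11). Cholesterol synthesis was called in the fit of all 8 libraries (adjusted p = 0.0319, range 0.00433 to 0.351). Under the scaling to identity genes camera called the cholesterol, unfolded protein, apoptosis and stress lists, all below other genes (adjusted p = 0.00433, 0.0151, 0.0104 and 0.0241). That scaling lowers all changes by a similar amount. The list medians were -1.89, -1.73, -1.60 and -2.62 there, against -1.503 over all genes. Under TMM they were -0.40, -0.24, -0.11 and -1.12, against -0.01. These calls therefore do not show that the lists moved further from other genes. Over the alternatives the unfolded protein, apoptosis and stress lists ranged from 0.0151 to 0.846, 0.0104 to 0.493 and 0.0241 to 0.48. Interleukin-2 and STAT5 targets counted 14 up and 6 down of 23 (adjusted p = 0.073, and 0.0439 without ILC2 co-cultured replicate 2, range 0.0439 to 0.833), with Ltb at 1.86 and Socs1 at -1.82. Both mitochondrially encoded genes measured rose.

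**Figure D3:**
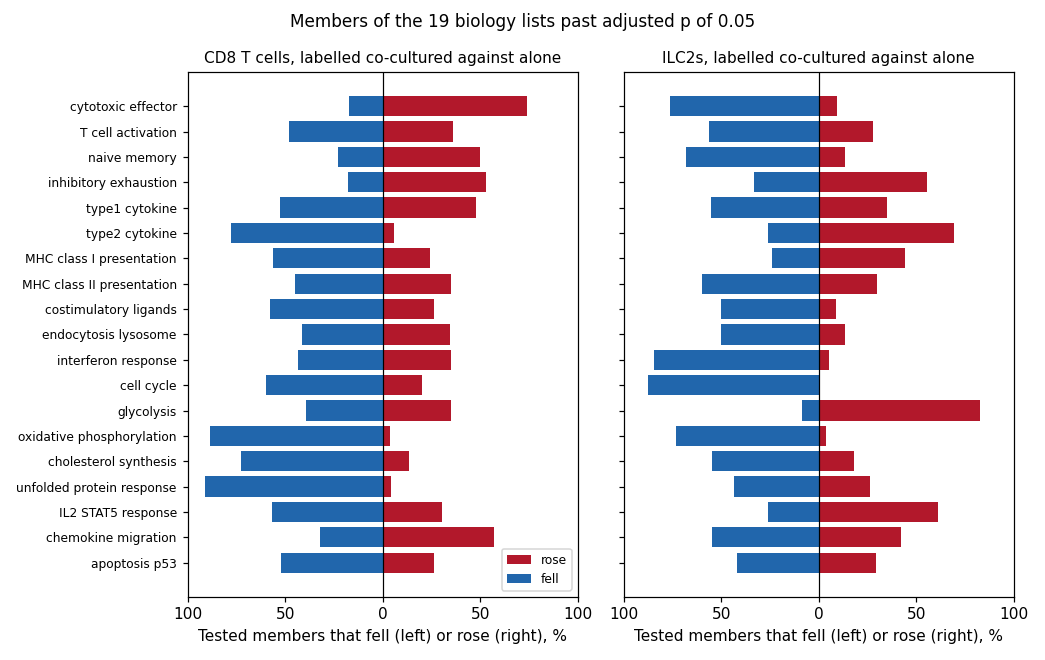
Percent of tested members of each of 19 biology lists that rose (right) or fell (left) in libraries labelled co-cultured, for CD8 T cells and for ILC2s, at an adjusted p under 0.05. Cytotoxic effector genes rose in 17 of 23 cases in CD8 T cells and fell in 16 of 21 in ILC2s, and cell cycle genes fell in 24 of 40 and 35 of 40.

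In total 5324 genes were higher and 5766 lower in ILC2s labelled co-cultured, 66.3% of the 16739 tested, and 2948 and 3805 changed at least 2-fold. Falls of at least 16-fold numbered 565 and rises of that size 24. Further calls that ended were those of endocytosis and T cell activation under a stricter low-count filter (adjusted p = 0.0751 and 0.0645) and of granulocytes and mast cells under the scaling to identity genes (0.128). Camera called 20 of 31 lists, 4 above and 16 below other genes, and with an estimated correlation 0, with 3 at an unadjusted p under 0.05, while fry called 26. Higher calls were 5324 of 11090, but 3.7% of all calls (499 higher and 13086 lower) when libraries were scaled to the ILC2 identity genes.

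For most lists the counts were the same when p-values were adjusted over the list alone. Adjusted over the list alone, the counts in CD8 T cells were 13 rising naive and memory genes, 7 rising class I genes, 11 rising endocytosis genes, 9 rising cell cycle genes, 11 falling glycolysis genes, 17 rising migration genes, 7 rising and 13 falling apoptosis genes and 10 falling stress genes. In ILC2s they were 36 falling cell cycle genes, 5 rising cholesterol genes, 11 falling unfolded protein response genes, 7 falling interleukin-2 and STAT5 targets, 2 rising and 7 falling dendritic cell genes and 36 rising ribosomal protein genes. Median, mean and camera direction differed in sign for the endocytosis, glycolysis and monocyte lists in CD8 T cells and for the inhibitory receptor and platelet lists in ILC2s.

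The responses of both cell types were compared directly. Of 15532 genes in both tables, 8324 differed in their log2 change, 3260 with a higher and 5064 with a lower change in ILC2s (edgeR interaction test, adjusted p under 0.05). Under TMM scaling the median difference over all genes was -0.12, against 0.001 with DESeq2 size factors and 0.043 with upper-quartile factors, so higher changes made up 39.2% of the calls under TMM, 46.9% and 49.4%. Among genes named for both cell types, Cd8a rose in CD8 T cells and fell in ILC2s (difference -5.90, SE 0.137). Cd74 (3.30, SE 0.159) and Csf2 (2.57, SE 0.412) fell further in CD8 T cells, and Cd80 (-2.09, SE 0.344) and Tyms (-1.43, SE 0.187) fell further in ILC2s. For Mki67 no difference passed the test (0.02, SE 0.163, edgeR adjusted p = 0.94). The list tests of this contrast were all chosen after the values were seen. Camera called 19 of 28 lists, and fry 26. With an estimated correlation 7 calls held, those of cytotoxic effectors, naive and memory genes, type 2 cytokines, interferon response and the ILC2, CD8 T cell and NK cell markers. Some of these lists share members, so the 7 calls are not separate results. Gata3 and Il5 are in the type 2 and ILC2 lists, Tcf7 in the naive and CD8 T cell lists and Gzma in the cytotoxic and NK cell lists. The libraries labelled ILC2 alone held T cell, macrophage and stroma transcripts. Differences such as that of Cd8a, and those of these lists, are therefore not shown to be responses of ILC2s themselves.

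Many genes moved alike under TMM, in a count that was not among the planned tests. Among 14835 genes tested in both cell types, 2501 were higher in both, against 1549.0 for independent lists, and 2639 were lower in both, against 1565.9. Opposite calls numbered 939 and 673, against 1555.6 and 1559.3. With ILC2 libraries scaled to the identity genes, 263 were higher in both, against 135.2 for independent lists, and 4313 lower in both, against 3753.2. Across genes, which are not independent replicates, the log2 changes had a Pearson's r of 0.27 and a Spearman's rho of 0.35. The comparisons share no library. Cycs, Tyms, Psme2, Cd80, Cd74 and Csf2 were among genes lower in both. Because the libraries labelled ILC2 alone held T cell, macrophage and stroma transcripts, genes moving alike are not shown to be a shared response to co-culture.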

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

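The tests of explanations in this part, and all tests of gene lists between the cell types, were chosen after the values were seen, while the edgeR interaction test of genes was planned. Genes named in both comparisons whose co-culture change differed between the cell types (edgeR interaction, log2 change in ILC2s minus that in CD8 T cells) were Csf2 (2.57), Cd74 (3.30), Psme2 (-0.46), Cd80 (-2.09), Tyms (-1.43), Cycs (-0.81) and Cd8a (-5.90). Csf2 and Cd74 fell in both cell types and fell further in CD8 T cells, and Psme2, Cd80, Tyms and Cycs fell in both and further in ILC2s.

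Gene lists with a different change by camera were lower in ILC2s, as the median member's difference, for cytotoxic effectors (-4.70), T cell activation (-0.84), naive and memory genes (-1.58), inhibitory receptors (-0.52), type 1 cytokines (-0.58), endocytosis (-0.45), interferon response (-1.61), cell cycle (-1.01) and chemokines and migration (-2.13). They were higher in ILC2s for type 2 cytokines (2.57), glycolysis (0.94), unfolded protein response (0.65) and interleukin-2 and STAT5 targets (0.52). The median over all genes was -0.12 under this scaling. With an estimated correlation the calls of cytotoxic effectors (adjusted p = 0.0146), naive and memory genes (0.0262), type 2 cytokines (0.0153) and interferon response (0.0493) held. The other calls named here were lost, with adjusted p from 0.0668 (type 1 cytokines) to 0.445 (endocytosis). CD8 T cell (-3.11), NK cell (-4.0) and ILC2 identity (1.6) markers differed as well (camera with an estimated correlation, adjusted p = 0.0148, 0.0262 and 0.0148). These marker lists share members with the naive and memory, cytotoxic and type 2 lists. Libraries labelled ILC2 alone held T cell, macrophage and stroma transcripts, so the gene and list differences are not shown to be responses of ILC2s.

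The libraries labelled ILC2 alone held transcripts of T cells, macrophages and stroma far above their levels in the libraries labelled ILC2 co-cultured. Scaling as the whole cause is argued against, since it would move every gene alike, while the log2 changes of the 43 tested T cell, NK cell, macrophage and stroma markers had quartiles of -4.57 and -2.06, a distance of 2.51 against an upper-quartile SE of 0.30. RNA from macrophages, stroma and other cells stays open, because the count of 41 of 43 markers (95.3%) lower in libraries labelled co-cultured restates the pattern and ILC2 identity genes were higher there (median 1.55). Sorting would be expected to remove those cells. T cell RNA is a candidate explanation for part of it, although sorting would be expected to remove T cells: 19 transcripts alike in both CD8 groups and nearly missing from ILC2s labelled co-cultured reached 11.6% to 90.7% of their CD8 level (median 32.6%, quartiles 22.9% and 44.5%), a wider spread than a single share of these T cells would give. An exchange of the alone and co-cultured labels was examined with 21 T cell transcripts that differ between the CD8 groups. They were placed between the CD8 level labelled alone (0) and labelled co-cultured (1), assuming the median share of 32.6%. Their median position in the libraries labelled ILC2 alone was 0.19, nearer the level labelled alone (quartiles -0.02 and 0.57). The medians were 0.18 for 10 transcripts higher in CD8 T cells labelled alone and 0.41 for 11 higher labelled co-cultured. An exchange of the ILC2 labels only would put the position near 1, so these values argue against it for these transcripts. An exchange of the labels of both cell types would put the position near 0. It cannot be told apart from other sources of T cells such as lung. A response of ILC2s themselves to co-culture was not tested.

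Ifng, Csf2, Lta, Tnf and further cytokine genes were lower in CD8 T cells labelled co-cultured. Under the labels as given, carry-over from the ILC2 culture would add RNA to the libraries labelled co-cultured and lower no cytokine gene except by dilution. If the CD8 labels were exchanged, carry-over is argued against: of 16 ILC2 identity genes with at least 50 CPM in every ILC2 library, the lower quartile stood at 0.553% of their ILC2 level in CD8 T cells labelled alone, and that share would give a median of 0.29% (highest 0.58%) of the level labelled alone over 10 of the fallen type 1 cytokine genes. Scaling as the whole cause is argued against too, as the log2 changes of the 11 fallen genes had quartiles of -3.73 and -0.73, a distance of 3.0 against an upper-quartile SE of 0.133. An exchange of the CD8 labels stays open. Of 37 transcripts abundant in ILC2 libraries and scarce in CD8 T cells, 21 (56.8%) were higher in the libraries labelled alone. That count cannot decide it, because many of the 37 were nearly missing from ILC2s labelled co-cultured. Examples were Spp1 (12247 CPM in ILC2s labelled alone and 8.04 in those labelled co-cultured) and Chil3 (2469 and 6.23). Such transcripts cannot trace RNA of ILC2s like those labelled co-cultured. The planned estimate over 8 ILC2 markers leaned to the libraries labelled alone. Its medians were 0.489% and 0.461% there against 0.207% and 0.204% labelled co-cultured, shares too low to settle it. A response of CD8 T cells to ILC2s stays open as well and was not tested.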

How the results depend on the processing

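The tests of lists in the interaction and their alternatives, the scaling to ILC2 identity genes, the counts of genes called in both cell types and the T cell share against ILC2s labelled co-cultured were chosen after seeing the data, and the other alternatives were planned. All 63 CD8 genes named kept their direction and their side of the threshold under every alternative that could test them. Of the 61 ILC2 genes named, 53 did. Requiring a log2 change of at least 1 lowered the counts to 1532 higher and 1711 lower in CD8 T cells and 2948 and 3805 in ILC2s, by construction. With an estimated correlation camera called 0 lists in either cell type, and fry, which asks another question, called 21 in CD8 T cells. In the interaction, the estimated correlation left 7 of 19 lists. Camera with an estimated correlation has 2 degrees of freedom per cell type and 4 in the interaction. This limits its calls, and its counts in the 2 settings cannot be compared. Scaled to ILC2 identity genes, ILC2s had 499 higher and 13086 lower genes, 263 genes were higher and 4313 lower in both cell types (2501 and 2639 under TMM), and the changes of Areg (-0.03, a member of the identity list), H2-K1 (-0.28), H2-Ab1 (-0.33), Icosl (-1.0) and Mki67 (-1.43) turned negative, since that scaling subtracts about the median identity change from each gene. The ILC2 share in CD8 libraries labelled co-cultured was 0.206% with markers 20 times higher, 0.166% with 100 times and 0.749% with 5 times, and the T cell share in libraries labelled ILC2 alone was 22.8%, 20.5% (1 marker) and 28.2%. The cause of these differences was not tested.

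Leaving out 1 library gave 4217 to 4520 higher and 4335 to 4572 lower genes and 11 to 14 lists in CD8 T cells, 4422 to 5222 and 5007 to 5847 genes and 18 to 20 lists in ILC2s, 7097 to 8429 genes and 18 to 20 lists in the interaction, and 2219 to 2587 genes higher and 2356 to 2651 lower in both cell types. The group left with a lone library is then assumed to vary like the other. DESeq2 called 4501 and 4426 genes in CD8 T cells, 5070 and 5250 in ILC2s and 7941 in the interaction, and no adjusted p was missing. Across genes, the deviations of same-numbered replicates from their group means had correlations of 0.031 (CD8 T cells) and 0.095 (ILC2s) between the 2 groups. These replicates share only a number. With a replicate block the counts were 4817 and 4915 genes and 12 lists in CD8 T cells, 5295 and 5761 genes and 20 lists in ILC2s, and 8457 in the interaction. Both ILC2 libraries labelled alone hold other lineages' transcripts, so no comparison without them could be made. Depth limits genes with few reads, such as Lox with 6 and 3 reads in the ILC2 libraries labelled co-cultured.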

Other observations

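The genes in this part, and the tests on them, were chosen after the values were seen. In CD8 T cells labelled co-cultured, 3 integrin genes and a chemokine receptor gene were higher than in those labelled alone, while 9 of the 28 listed chemokine and migration genes fell. Itgae, encoding the CD103 chain that binds E-cadherin, went from 18.9 to 105.3 CPM (log2 change 2.40), Itga4 from 15.0 to 72.3 CPM (2.19), Itgb7 from 380.0 to 1255 CPM (1.64) and Ccr2 from 2.88 to 35.4 CPM (3.53). These 4 genes passed the edgeR test and kept their direction and call under every alternative that could test them.

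Ccr9 is known as a gene induced by retinoic acid in T cells, and the hypothesis was that other such genes moved with it. Of 12 tested genes listed for retinoic acid response, 11 rose in CD8 T cells labelled co-cultured, with a median log2 change of 2.56, among them Tgm2 (53.8 to 774.8 CPM), Lztfl1 (32.4 to 346.2 CPM), Hic1 (18.5 to 147.1 CPM) and Dhrs3 (2.70 to 14.2 CPM), while Stra6 fell. Because the list was written with these values in view, the count cannot decide whether retinoic acid was the cause. Carry-over from the ILC2 culture is argued against: the lower quartile of 16 abundant ILC2 identity genes stood at 0.225% of their ILC2 level in CD8 T cells labelled co-cultured, a share that would give a median of 0.29% (highest 1.27%) of the level of the 11 genes. In the ILC2 libraries 4 of 15 listed genes rose and 7 fell.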
